A study of Mus musculus with 9 samples.

How the data were processed

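Whole-lung RNA of 9 mouse libraries was analysed, 3 from control mice, 3 from bleomycin-challenged mice and 3 from bleomycin-challenged mice treated with inhaled particles (LNP), all at day 21. Poly(A) RNA was made into strand-marked paired-end libraries, per the labels' protocols. The submitters' processing notes name fastp, StringTie and edgeR as the authors' tools, with no versions. The aligner and the genome build are not given in the sources used here. The deposited tables hold whole-number counts per gene and per transcript and FPKM values per gene, per the file headers, for 32671 genes and 149138 transcripts. How the deposited counts were derived, and whether they used the strand, is not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain. In the deposited table gene counts equalled the sums of transcript counts in all 9 libraries for 32651 genes, and the other 20 differed by at most 1 count. FPKM values, scaled by the authors and named as such in the file headers, served only as an alternative unit. Of 30696 genes shared with a GRCm38 annotation only 542 lay at the same position, so coordinates are those of the deposited table and no reference coordinates were used.

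Totals of gene counts were 60074344, 69404903 and 67319811 in control, 67234176, 66888346 and 66185225 in bleomycin, and 68882873, 58062865 and 56047830 in LNP libraries. The mitochondrial share of counts was 1.78% to 2.80% in control, 1.49% to 1.58% in bleomycin and 1.83% to 1.90% in LNP libraries. No pair of libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 32.7. Symbols on more than 1 gene identifier numbered 185, and tests were run by identifier.

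Groups and replicate numbers were taken from the labels. The test of each comparison was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the deposited gene counts of all 9 libraries in 1 fit, with TMM scaling and the filterByExpr filter on low counts, which kept 20794 genes and left out 11877. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold, and every adjusted p of a gene is from this test unless another tool is named. CPM values use TMM-scaled library sizes. The 30 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 30 lists of a comparison. Each list was also tested with the correlation estimated per list, and with fry. The groups, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined.

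The rule named, per comparison, the 8 largest rises and 8 largest falls among called genes without overlap between the groups and with a mean of at least 5 CPM in the higher group, passing over unnamed gene models, pseudogenes and antigen receptor segments. It also named up to 4 called members with the smallest p per list, all STING pathway members, and for the reversal the 8 genes with the smallest LNP against bleomycin p in each direction. Some results selected by the rule are not reported here. A few list members outside the rule are named where 5 or fewer passed or as the library and squamous markers, chosen after their values were seen. A first version of the symbol filter passed over Ighd, a constant region gene, as if it were a D segment, and this was corrected. Where a group had no count, folds were computed against a floor of 3 counts over the group, which covers counting error only.

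Alternatives were DESeq2 1.42.0, relative log expression scaling, no count filter, fits of only the 2 groups compared, the replicate number as a block, a minimum of 2-fold, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for 15478 genes with a mean FPKM of at least 0.5, the same with no filter, leaving out 295 immunoglobulin, haemoglobin and mitochondrial genes, 46941 transcripts tested singly, and leaving out each library in turn. Library-size scaling and limma-voom with library weights were added after seeing the data. Chance levels for the reversal and for the shared controls came from 20 simulations each of negative binomial counts. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

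The scripts were tested on simulated counts for 20794 genes with 100 genes changed 2-fold and 100 changed 4-fold. edgeR recovered 22% of the 2-fold changes in each comparison, 65% of the 4-fold changes for bleomycin against control and 66% for LNP against bleomycin and for LNP against control, with 9, 5 and 4 false calls. DESeq2 recovered 43%, 50% and 48% of the 2-fold changes and 77%, 81% and 79% of the 4-fold changes, with 58, 51 and 37 false calls. A list of extracellular matrix genes shifted 2-fold was called by camera at adjusted p-values of 1.21e-30, 4.08e-29 and 1.14e-32, with 0 other lists called. The simulated genes were drawn independently, so false list calls in real data, where genes of a list correlate, were not measured by it. Absent calls of genes at a true 2-fold change were common in edgeR at this number of libraries.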

Results

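Messenger RNA of whole lung was sequenced at day 21 in 3 groups of C57BL/6 mice with 3 libraries each. Control mice received saline. The bleomycin group received bleomycin, a DNA-damaging drug used to provoke lung fibrosis. The remaining group, here called LNP, was challenged with bleomycin and treated with inhaled lipid nanoparticles labelled as carrying mCas9 and gSting, where Cas9 is a nuclease that cuts DNA at a site set by its guide. The series title places the particles as a macrophage-targeted way to modulate the STING pathway, which senses DNA in the cytosol, in lung fibrosis. The deposited gene counts summed to between 56047830 and 69404903 per library, and 20794 genes were tested. The labels do not say that the 3 samples of a group are separate animals, so p-values measure the spread between these samples. Values after ± are SD over n = 3 libraries for counts scaled to CPM and SE for log2 fold changes.

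Control and bleomycin libraries lay at opposite ends of the first principal component, with LNP replicates 1 and 2 between them and LNP replicate 3 near the bleomycin libraries. This component held 47.15% of the variance. Control libraries correlated with each other at r = 0.973 to 0.980 on log2 CPM across genes and bleomycin libraries at 0.970 to 0.979, whereas LNP libraries reached only 0.933 for their least similar pair. LNP replicate 3 stood apart from the other 8 libraries. It held skeletal muscle transcripts such as Acta1 at 3447 CPM, against at most 2.37 CPM in any other library, and squamous keratins such as Krt4 at 767 CPM, against at most 3.89 CPM elsewhere. Counts are therefore also given without this library where it changes them by over 1.5 times.

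**Figure D1:**
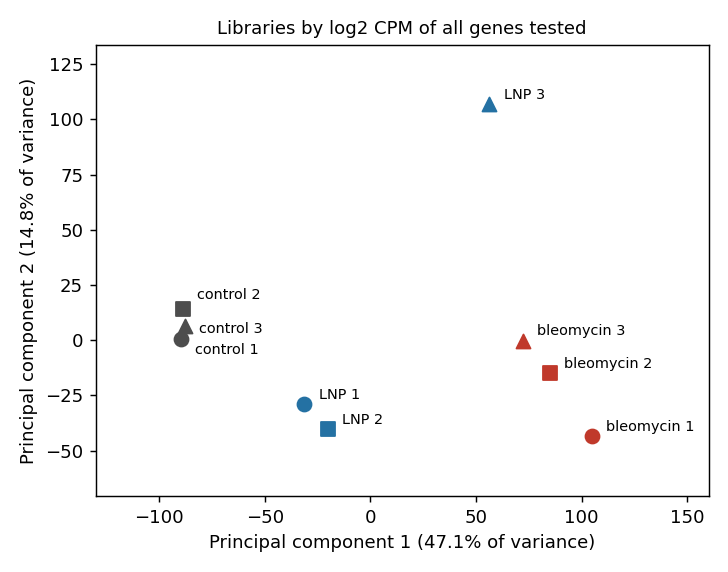
Each point is 1 library placed by the first (x axis) and second (y axis) principal component of log2 CPM over 20794 genes, with the group by colour and the replicate by marker. LNP replicate 3 lies at 106.8 on the second component, while the other 8 libraries lie between -43.6 and 14.0.

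Sting1, the gene named by the guide, was not lower in LNP lung. The level was 18.4, 23.9 and 20.9 CPM in the control libraries, 53.8, 41.5 and 40.5 CPM in the bleomycin libraries and 51.8, 62.0 and 44.3 CPM in the LNP libraries. The means were 21.1 ± 2.75 CPM in control, 45.3 ± 7.4 CPM in bleomycin and 52.7 ± 8.9 CPM in LNP libraries. In the files Sting1 (ENSMUSG00000024349) lies on chromosome 18 from 35866732 to 35873542 on the minus strand, in coordinates whose genome build is not given in the sources used here. It rose 2.15-fold after bleomycin (log2 fold change 1.10 ± 0.18, adjusted p = 0.0016). The difference between LNP and bleomycin was 0.22 on the log2 scale, with a 95% interval from -0.17 to 0.61 and an adjusted p of 0.48 in edgeR's quasi-likelihood test. An exact two-sided permutation test of that difference gave p = 0.3, where 0.1 is the smallest p that 3 against 3 libraries allow. Against control, Sting1 was 2.50-fold higher in LNP lung (log2 fold change 1.32 ± 0.18, adjusted p = 0.0029). One transcript, ENSMUST00000115728, held 75.4% of the Sting1 counts and averaged 15.2 ± 1.76 CPM in control, 30.1 ± 1.99 CPM in bleomycin and 44.1 ± 10.1 CPM in LNP libraries. ENSMUST00000235495, ENSMUST00000237919 and ENSMUST00000235496, with 12.1%, 6.37% and 5.24% of the counts, had lower means in LNP than in bleomycin libraries. They went from 6.59 ± 3.79 to 4.26 ± 1.39 CPM, from 5.12 ± 2.58 to 1.44 ± 1.34 CPM and from 3.01 ± 2.98 to 2.34 ± 1.05 CPM. Each remaining transcript held at most 0.424% of the counts. RNA of whole lung does not measure how much Sting1 DNA was edited or in which cells. A limma-voom fit with a quality weight per library, chosen after seeing the data, put Sting1 0.45 higher in LNP than in bleomycin with an adjusted p of 0.0024. The weights in it were 0.66, 9.97 and 0.84 for bleomycin replicates 1, 2 and 3 and 0.13 for LNP replicate 3. Its bleomycin values thus rest largely on replicate 2. Over the alternatives other than the 2-fold minimum the adjusted p ran from 0.0024 to 0.87, the latter without LNP replicate 2.

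**Figure D2:**
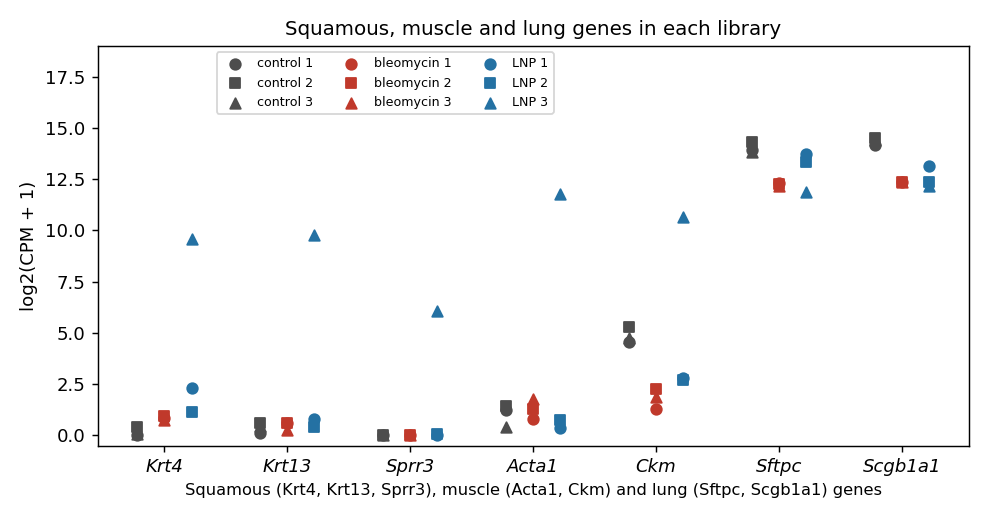
Points give log2(CPM + 1) (y axis) of 3 squamous, 2 muscle and 2 lung genes (x axis) in each of the 9 libraries, with the group by colour and the replicate by marker. Krt4, Krt13, Sprr3, Acta1 and Ckm stand far above all other libraries in LNP replicate 3, with Krt13 at 866 CPM, while Sftpc at 3760 CPM and Scgb1a1 at 4520 CPM are the lowest of the LNP group there.

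**Figure D3:**
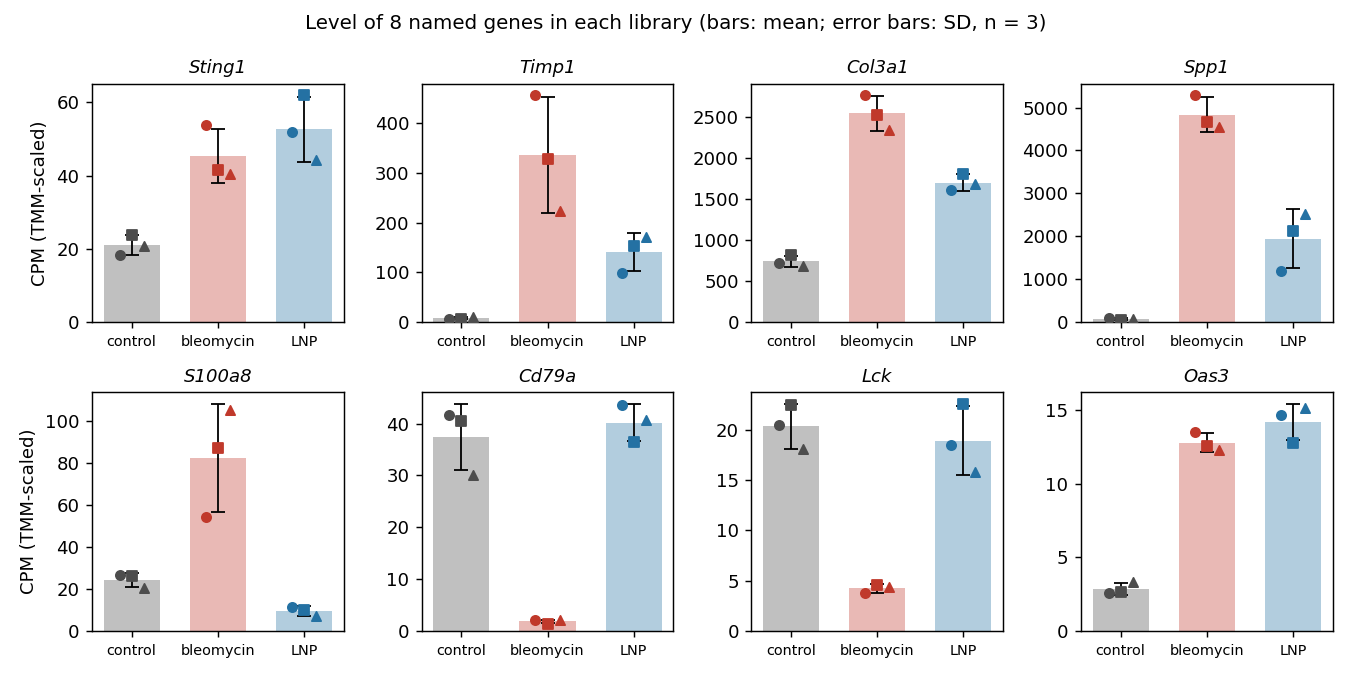
Bars show the mean CPM per group (y axes, CPM on TMM-scaled library sizes, from 0), error bars the SD over 3 libraries, and points the single libraries. Sting1 was at 40.5 to 53.8 CPM in the bleomycin libraries and 44.3 to 62.0 CPM in the LNP libraries, while Cd79a fell to at most 2.03 CPM after bleomycin and was at 36.4 CPM or more with LNP.

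The first comparison asked what bleomycin had done to whole lung by day 21. Most matrix and TGF-beta signalling genes rose together with markers of recruited macrophages, an injured alveolar epithelium and dividing cells, while 18 of 19 T and NK cell, 11 of 17 B and plasma cell, all 15 ciliated, 9 of 14 club and secretory and 12 of 19 endothelial markers fell. Timp1, an inhibitor of matrix metalloproteinases, went from 7.69 ± 1.95 to 336 ± 117 CPM (log2 fold change 5.45 ± 0.35, adjusted p = 4.0e-05). Spp1, the osteopontin gene of scar-associated macrophages, went from 74.4 ± 24.2 to 4829 ± 406 CPM (log2 fold change 6.02 ± 0.36, adjusted p = 3.0e-05). Cd79a, a B cell receptor gene, went from 37.4 ± 6.38 to 1.81 ± 0.36 CPM (log2 fold change -4.37 ± 0.21, adjusted p = 1.3e-05). In all, 3159 genes were higher and 3843 lower in bleomycin than in control lung at an adjusted p under 0.05, and 11533 genes (55.5%) had no overlap between the groups, where chance gives 10%.

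The largest rises included Mmp10, a matrix metalloproteinase, and Fgf23, a phosphate-regulating hormone gene. Both had no count in any control library, and against a floor of 3 counts over the control group they were at least 669-fold and 420-fold higher. Ereg, an epidermal growth factor receptor ligand, went from 0.287 ± 0.255 to 61.9 ± 45.9 CPM. Arg1, the arginase of alternatively activated macrophages, went from 1.4 ± 0.223 to 156 ± 60.9 CPM. Prss22, Il6, Saa3 and Chl1 completed the 8 largest rises, with log2 fold changes from 6.43 to 6.71. The 8 largest falls were Cd209a, a dendritic cell lectin gene, Car3 and Plin1, both abundant in fat cells, Slc7a10, Colq, Ankrd63, Asgr1 and the B cell factor Pax5. Their log2 fold changes ran from -6.57 for Cd209a to -5.12 for Pax5.

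Of the extracellular matrix list, 23 of 25 measured members passed the test as higher and 1 as lower (23 and 1 adjusted over the list alone). The median log2 fold change was 1.96 (camera adjusted p = 1.3e-13, and adjusted p = 0.15 with an estimated correlation). Tnc, a tenascin of healing wounds, rose from 24 ± 1.48 to 817 ± 312 CPM, Fn1 from 439 ± 74.1 to 4613 ± 135 CPM, and the fibrillar collagen Col3a1 from 739 ± 64.8 to 2544 ± 214 CPM. TGF-beta signalling genes, which drive fibroblast activation, had 12 of 18 members higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 2.9e-05, and adjusted p = 0.15 with an estimated correlation). Inhba rose by 4.75 ± 0.48 on the log2 scale. Among myofibroblast and activated fibroblast genes only 4 of 15 were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.032, and adjusted p = 0.51 with an estimated correlation). The 4 were Grem1, Lrrc15, Cthrc1 and Runx1. Of the resting alveolar fibroblast genes, 7 of 12 were lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.0034, and adjusted p = 0.31 with an estimated correlation), with Inmt down by -2.92 ± 0.25 and Tcf21 by -2.38 ± 0.41 on the log2 scale.

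The STING pathway list split. Of its members, 6 of 16 were higher (Sting1, Trex1, Enpp1, Ddx41, Ifi204 and Nlrc3) and 2 lower (Irf3 and Rnf5), the same counts as adjusted over the list alone, and the list was not called (camera adjusted p = 0.11). Ifi204, a DNA sensor gene, rose from 4.01 ± 1.89 to 21.9 ± 2.44 CPM (log2 fold change 2.45 ± 0.39, adjusted p = 0.0016). Cgas, the enzyme upstream of STING, was at 1.88 ± 0.44 CPM in control and 1.95 ± 0.654 CPM in bleomycin (adjusted p = 0.92). Interferon-stimulated genes also went both ways, with 8 of 30 higher and 4 lower (9 and 4 adjusted over the list alone) and no call (camera adjusted p = 0.16). Their median log2 fold change was -0.0013 although the test and the mean pointed up. Oas3 rose by 2.16 ± 0.17, Cxcl10 by 2.48 ± 0.31 and Irf7 by 1.95 ± 0.27, whereas Stat2 fell by 0.83 on the log2 scale. NF-kB inflammatory genes had 16 of 22 members higher and none lower, the same counts over the list alone (camera adjusted p = 4.0e-06, and adjusted p = 0.24 with an estimated correlation), led by the monocyte attractants Ccl2 and Ccl7.

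Markers of monocyte-derived macrophages had 14 of 21 members higher and 2 lower (16 and 2 adjusted over the list alone, camera adjusted p = 6.6e-08, and adjusted p = 0.15 with an estimated correlation), with Trem2 from 4.09 ± 1.15 to 104 ± 3.64 CPM and the complement gene C1qa from 53.3 ± 7.43 to 429.6 ± 7.7 CPM. Alveolar macrophage markers split into 5 higher and 4 lower of 15, with no call (camera adjusted p = 0.93, upward although the median and mean were below 0). Neutrophil markers had 7 of 15 members higher and 1 lower (8 and 1 over the list alone, camera adjusted p = 0.0036, and adjusted p = 0.24 with an estimated correlation), including Trem1 and Retnlg. T and NK cell markers fell in 18 of 19 cases, also over the list alone, with a median of -2.10 (camera adjusted p = 6.3e-10, and adjusted p = 0.15 with an estimated correlation). Lck, the proximal T cell receptor kinase, went from 20.4 ± 2.23 to 4.23 ± 0.453 CPM. B and plasma cell markers fell in 11 of 17 cases and rose in 3, also over the list alone (camera adjusted p = 7.2e-06, and adjusted p = 0.068 with an estimated correlation). The antibody genes of the list differed. Ighm went from 174 ± 53.4 to 52.5 ± 7.96 CPM and Igkc from 109 ± 13.6 to 96.7 ± 7.95 CPM. Jchain went from 14.35 ± 2.95 to 18.1 ± 3.77 CPM and Ighg1 from 0.547 ± 0.173 to 1.84 ± 0.809 CPM. MHC class II genes fell in 7 of 8 cases (8 over the list alone, camera adjusted p = 0.00055, and adjusted p = 0.28 with an estimated correlation).

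In the epithelium, all 13 genes of the transitional alveolar state rose, also over the list alone, with a median of 2.24 (camera adjusted p = 3.7e-09, and adjusted p = 0.16 with an estimated correlation), among them Cldn4 from 12 ± 1.76 to 143 ± 40.2 CPM. Alveolar type 2 markers fell in 9 of 13 cases and rose in 1, the protease Ctsh (10 and 1 over the list alone, camera adjusted p = 0.0069, and adjusted p = 0.47 with an estimated correlation). Alveolar type 1 markers had 5 of 13 higher and 1 lower, also over the list alone, with no call (camera adjusted p = 0.097). All 15 ciliated cell markers fell, also over the list alone (camera adjusted p = 9.6e-09, and adjusted p = 0.16 with an estimated correlation), with Hydin from 25.7 ± 2.84 to 3.99 ± 0.223 CPM. Club and secretory cell markers fell in 9 of 14 cases (10 over the list alone, camera adjusted p = 0.00014, and adjusted p = 0.2 with an estimated correlation), with Scgb1a1, the most abundant transcript of the control libraries, from 21165 ± 2587 to 5249 ± 69.4 CPM. Endothelial markers fell in 12 of 19 cases and rose in 2 (13 and 2 over the list alone, camera adjusted p = 0.0069, and adjusted p = 0.44 with an estimated correlation).

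Cell cycle genes rose in 20 of 23 cases, also over the list alone (camera adjusted p = 6.3e-10, and adjusted p = 0.2 with an estimated correlation), and p53 targets in 16 of 18, with 16 higher and 1 lower over the list alone (camera adjusted p = 3.3e-07, and adjusted p = 0.068 with an estimated correlation). Psrc1 and Eda2r led the p53 list, at 2.87 ± 0.20 and 2.22 ± 0.23 on the log2 scale. Immediate early genes rose in 13 of 14 cases and fell in 1, also over the list alone (camera adjusted p = 8.9e-07, and adjusted p = 0.2 with an estimated correlation). Cholesterol genes rose in 6 of 19 cases and fell in 1, also over the list alone (camera adjusted p = 0.022, and adjusted p = 0.49 with an estimated correlation). Markers of fat and heart muscle also differed between the groups, and the tissue they came from was not tested. Adipocyte markers fell in 7 of 9 measured cases (camera adjusted p = 0.00032, and adjusted p = 0.15 with an estimated correlation) and cardiac muscle markers in 9 of 12 (camera adjusted p = 0.00015, and adjusted p = 0.32 with an estimated correlation), in both lists also over the list alone. The cardiac gene Actc1 went from 299 ± 54.2 to 46.7 ± 25.9 CPM and the fat gene Adipoq from 12.6 ± 1.36 to 1.23 ± 0.747 CPM. Mitochondrial transcripts fell in 5 of 11 cases (6 over the list alone, camera adjusted p = 0.0076, and adjusted p = 0.47 with an estimated correlation), and thymocyte markers in all 4 measured, also over the list alone (camera adjusted p = 0.018, and adjusted p = 0.2 with an estimated correlation). Of the unfolded protein response, Creld2, Herpud1 and Pdia4 fell among 15 genes, and 1 was lower adjusted over the list alone. No erythroid or skeletal muscle gene passed in edgeR, where 3 of 8 and 0 of 11 had an unadjusted p under 0.05 and DESeq2 called 1 and 0. These 3 lists were not called, with camera adjusted p-values of 0.52, 0.11 and 0.67.

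Of the 30 lists, 23 were called after bleomycin with the preset correlation of 0.01 and none with an estimated correlation, where the smallest adjusted p was 0.068. The counts of single genes and not the list p-values therefore carry the description above. Dividing the 6 libraries into mixed groups of 3 still called up to 18 lists. Each mixed split keeps part of the difference between the groups, so those calls do not measure a chance level. Leaving out bleomycin replicate 1 gave 1951 higher and 2479 lower genes, bleomycin replicate 2 gave 1963 and 2412, and control replicate 1 gave 2082 higher genes. Of the 129 gene results selected by the naming rule for this comparison, 119 passed the test whichever library was left out. Leaving out LNP replicate 3, which enters the shared estimate of the spread, raised the higher myofibroblast genes to 8 and the higher interferon-stimulated genes to 13. It also put 2 unfolded protein response genes and 1 skeletal muscle gene higher. Lower were 3 skeletal muscle, 3 erythroid, 2 neutrophil, 2 alveolar type 1 and 1 NF-kB inflammatory gene. The exceptions named above are Trex1, Rnf5, Ddx41, Herpud1 and Pdia4, which passed in 7, 6, 4, 4 and 2 of 9 such fits. Of the thymocyte markers, Ccr9, Dntt and Themis passed in 5, 3 and 3 of them.

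The second comparison asked how bleomycin-challenged lung differed with the inhaled particles. No particle without the guide was analysed here, so effects of the guide and of the particle cannot be separated. Most B and T cell markers were higher in LNP than in bleomycin lung (15 of 17 and 13 of 19), and 7 of 15 neutrophil markers were lower. Cd79a, part of the B cell receptor, was at 1.81 ± 0.36 CPM in bleomycin and 40.2 ± 3.6 CPM in LNP lung (log2 fold change 4.47 ± 0.21, adjusted p = 1.1e-05). S100a8, an abundant neutrophil alarmin, was at 82.5 ± 25.9 and 9.5 ± 2.19 CPM (log2 fold change -3.12 ± 0.27, adjusted p = 0.00054). Several matrix genes were lower in LNP than in bleomycin lung and several interferon-stimulated genes higher, with calls that depended on which libraries entered. In all, 891 genes were higher and 389 lower, and 6211 genes (29.9%) had no overlap between the groups, where chance gives 10%.

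When LNP replicate 3 was left out the counts were 2987 higher and 2297 lower, and all 1280 genes called with it stayed called in the same direction. Without bleomycin replicate 2 they were 84 and 18, and leaving out any other single library except control replicate 2 moved at least 1 of the counts by over 1.5 times, to between 193 and 545 higher and between 41 and 270 lower genes. Of the 75 gene results selected by the naming rule for this comparison, 23 passed the test whichever library was left out. Among these were the B cell genes Cd79a, Cd79b, Blk, Pax5, Spib, Ighd and Fcmr, the T cell genes Lck, Cd3d, Cd3e and Trac, the class II genes H2-Oa and H2-Ob, the neutrophil-associated genes S100a8, S100a9, Retnlg, Trem1, Il1r2, Stfa2l1 and Olfm4, and the growth-restraining genes Btg2 and Mxd1. Scaling by library size alone in place of TMM gave 1282 higher and 253 lower genes and moved the median log2 fold change of all genes to 0.16, from 0.04.

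The largest rises included Rptn, Ighg2c, Mb, Pla2g2d, Cd209a, Mybpc2 and Pax5, with log2 fold changes from 4.93 to 6.61. The genes Ighg2c, Cstdc4 and Stfa2l1 belong to families of near-identical copies, so their values are uncertain as far as counting split reads between copies. Rptn, an epidermal gene, and Mb and Mybpc2, both muscle genes, had most of their LNP signal in replicate 3, at 20.9, 493 and 149.6 CPM, and their log2 fold changes without it were 2.79, 1.82 and 3.34. The largest falls were Cstdc4, Stfa2l1, Retnlg, Il1r2, S100a8, Apold1, S100a9 and Trem1, of which all but Apold1 are known from neutrophils or granulocytes. Their log2 fold changes ran from -4.38 to -2.88. Neutrophil markers were lower in 7 of 15 cases (9 lower and 2 higher over the list alone, camera adjusted p = 7.5e-06, and adjusted p = 0.18 with an estimated correlation).

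Of the extracellular matrix list, 8 of 25 members were lower in LNP than in bleomycin lung and 1 was higher (19 and 1 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 9.2e-10, and adjusted p = 0.2 with an estimated correlation). With LNP replicate 3 left out, 20 members were lower and the median was -1.02. Tnc went from 817 ± 312 to 250.4 ± 98.3 CPM (log2 fold change -1.71 ± 0.33, adjusted p = 0.021), Col6a3 from 867 ± 17.7 to 347 ± 149.5 CPM and Col12a1 from 166 ± 20.4 to 76.9 ± 22.5 CPM, and each of these 3 calls passed in 5 of the 9 fits that left out 1 library. TGF-beta signalling genes had 4 of 18 lower (7 over the list alone, camera adjusted p = 7.0e-05, and adjusted p = 0.18 with an estimated correlation), among them Inhba, Smad4 and Itgav. These passed in 5, 2 and 2 of the 9 fits that left out 1 library. Of the myofibroblast list only Thy1 passed, as higher (log2 fold change 0.95 ± 0.14, adjusted p = 0.0084), although the list was called as lower (camera adjusted p = 0.003, and adjusted p = 0.54 with an estimated correlation). Of its 15 members, 12 were lower and 1 higher without LNP replicate 3.

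No member of the STING pathway list passed the test between LNP and bleomycin, and none did over the list alone (camera adjusted p = 0.9975, with a median of -0.0065 against an upward test). At an unadjusted p under 0.05, 3 of the 16 members passed in edgeR, while DESeq2 called 0 and limma on FPKM 0. The limma-voom fit with library weights, whose bleomycin values rest largely on replicate 2, called 12. Without LNP replicate 3, edgeR called 2 as higher and 2 as lower. Ikbke was at 11.2 ± 2.98 and 17.4 ± 3.25 CPM (adjusted p = 0.11) and Cgas at 1.95 ± 0.654 and 3.08 ± 0.579 CPM (adjusted p = 0.25). Interferon-stimulated genes were higher in LNP lung in 5 of 30 cases and lower in none (13 and 0 over the list alone), with a median of 0.57 (camera adjusted p = 4.2e-06, and adjusted p = 0.26 with an estimated correlation). The counts were 18 higher and 1 lower without LNP replicate 3. Stat2 went from 24.9 ± 1.64 to 42.1 ± 2.99 CPM and Oas1a from 17 ± 1.65 to 37.7 ± 12.5 CPM. Stat2 passed in 8 and Oas1a, Dhx58 and Xaf1 in 3, 3 and 2 of the 9 fits that left out 1 library. NF-kB inflammatory genes had 1 of 22 lower, Il1b from 41.3 ± 4.24 to 9.02 ± 5.98 CPM (9 lower and 1 higher over the list alone, camera adjusted p = 0.0036, and adjusted p = 0.57 with an estimated correlation). That list had 7 lower genes but was not called without LNP replicate 3 (camera adjusted p = 0.11).

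B and plasma cell markers were higher in 15 of 17 cases (16 over the list alone), with a median of 3.36, and this was the only list of the 17 called that kept its call with an estimated correlation (camera adjusted p = 8.0e-22, and adjusted p = 0.0023 with an estimated correlation). T and NK cell markers were higher in 13 of 19 cases (19 over the list alone, camera adjusted p = 5.9e-15, and adjusted p = 0.15 with an estimated correlation) and MHC class II genes in 7 of 8 (8 over the list alone, camera adjusted p = 2.1e-07, and adjusted p = 0.19 with an estimated correlation). H2-Oa went from 1.97 ± 0.0662 to 11.2 ± 0.304 CPM. Monocyte-derived macrophage markers had 2 higher (Fabp5 and Cx3cr1) and 2 lower (Spp1 and Lpl) of 21, with no call (camera adjusted p = 0.21, downward although the mean was above 0). The counts without LNP replicate 3 were 11 lower and 4 higher (camera adjusted p = 0.039). Spp1 went from 4829 ± 406 to 1945 ± 684 CPM and passed in 3 of the 9 fits that left out 1 library. Fabp5, Cx3cr1 and Lpl passed in 8, 5 and 1 of them. Among alveolar macrophage markers Chil3, Mrc1 and Ctsk were lower and Cidec higher, with no call (camera adjusted p = 0.51, downward although the mean was above 0).

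Ciliated cell markers were higher in 11 of 15 cases (14 over the list alone, camera adjusted p = 4.8e-10, and adjusted p = 0.18 with an estimated correlation), with Foxj1, the ciliogenesis factor, from 54.4 ± 5.9 to 118 ± 20 CPM. Foxj1, Ccdc40, Dynlrb2 and Hydin passed in 8 of the 9 fits that left out 1 library, all but the fit without bleomycin replicate 2. Of the club and secretory markers only Cyp2f2 passed, as higher (8 over the list alone, camera adjusted p = 0.00012, and adjusted p = 0.24 with an estimated correlation). Transitional epithelium genes were lower in 4 of 13 cases (9 lower and 1 higher over the list alone, camera adjusted p = 0.00017, and adjusted p = 0.37 with an estimated correlation), among them Krt7 and Plaur. No alveolar type 2 marker passed in edgeR over all genes, while 10 of 13 had an unadjusted p under 0.05 and DESeq2 called 5 (5 higher and 1 lower over the list alone, camera adjusted p = 0.034, and adjusted p = 0.68 with an estimated correlation), and 11 were higher and 1 lower without LNP replicate 3. Alveolar type 1 markers had 2 of 13 lower, Gprc5a and Emp2 (2 over the list alone, camera adjusted p = 0.067). These passed in 5 and 3 of the 9 fits that left out 1 library. Endothelial markers had 2 of 19 lower, Gpihbp1 and Vwf, which passed in 1 and 2 of those 9 fits. The endothelial list had a median and mean above 0 against a downward test (camera adjusted p = 0.79). Leaving out LNP replicate 3 turned this into a call as higher (camera adjusted p = 0.039), with 11 higher and 2 lower. Immediate early genes were lower in 9 of 14 cases (13 over the list alone, camera adjusted p = 3.1e-10, and adjusted p = 0.18 with an estimated correlation), with Fos from 194 ± 36.1 to 38.5 ± 23.9 CPM. Adipocyte markers had 1 of 9 higher, Plin1 (7 over the list alone, camera adjusted p = 0.00087, and adjusted p = 0.18 with an estimated correlation). The fit without LNP replicate 3 put 9 transitional epithelium genes and 8 TGF-beta genes lower, and 6 club and secretory, 4 adipocyte, 3 neutrophil, 3 alveolar type 1, 2 TGF-beta and 5 alveolar macrophage genes higher.

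Skeletal muscle markers were called as higher with no member past the gene-wise test over all genes (11 of 11 over the list alone, camera adjusted p = 0.04, and adjusted p = 0.68 with an estimated correlation), while DESeq2 called 0 of the 11. Without LNP replicate 3 the direction turned (camera adjusted p = 0.78, median -0.42). Thymocyte markers were also called as higher, with no member past the test over all genes (3 of 4 over the list alone and 2 by DESeq2, camera adjusted p = 0.037, and adjusted p = 0.26 with an estimated correlation). The other lists were not called in this comparison, at camera adjusted p-values of 0.12 for the cell cycle, 0.38 for p53 targets, 0.11 for cholesterol genes, 0.36 for resting fibroblasts, 0.38 for cardiac muscle, 0.38 for mitochondrial transcripts, 0.82 for erythroid cells and 0.63 for the unfolded protein response. The last of these had a downward test with a median and mean above 0, and the erythroid list a downward test with a mean above 0. None of these lists lost or gained a call without LNP replicate 3. That fit did put 6 resting fibroblast, 2 cell cycle, 2 cholesterol, 2 mitochondrial, 2 unfolded protein response, 2 skeletal muscle, 2 thymocyte and 1 erythroid gene higher. It put 4 cholesterol, 3 p53, 2 cardiac muscle, 2 skeletal muscle, 1 cell cycle and 1 unfolded protein response gene lower. At an unadjusted p under 0.05, 3 of 23 cell cycle genes, 7 of 18 p53 targets, 6 of 12 resting fibroblast genes, 2 of 12 cardiac, 2 of 11 mitochondrial, 1 of 15 unfolded protein response and 0 of 8 erythroid genes passed in edgeR, none of them past the adjusted threshold, and DESeq2 called 1, 3, 4, 0, 2, 1 and 0 of them. Among cholesterol genes Dhcr7 was higher and Hsd17b7 lower (1 higher and 2 lower adjusted over the list alone).

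**Figure D4:**
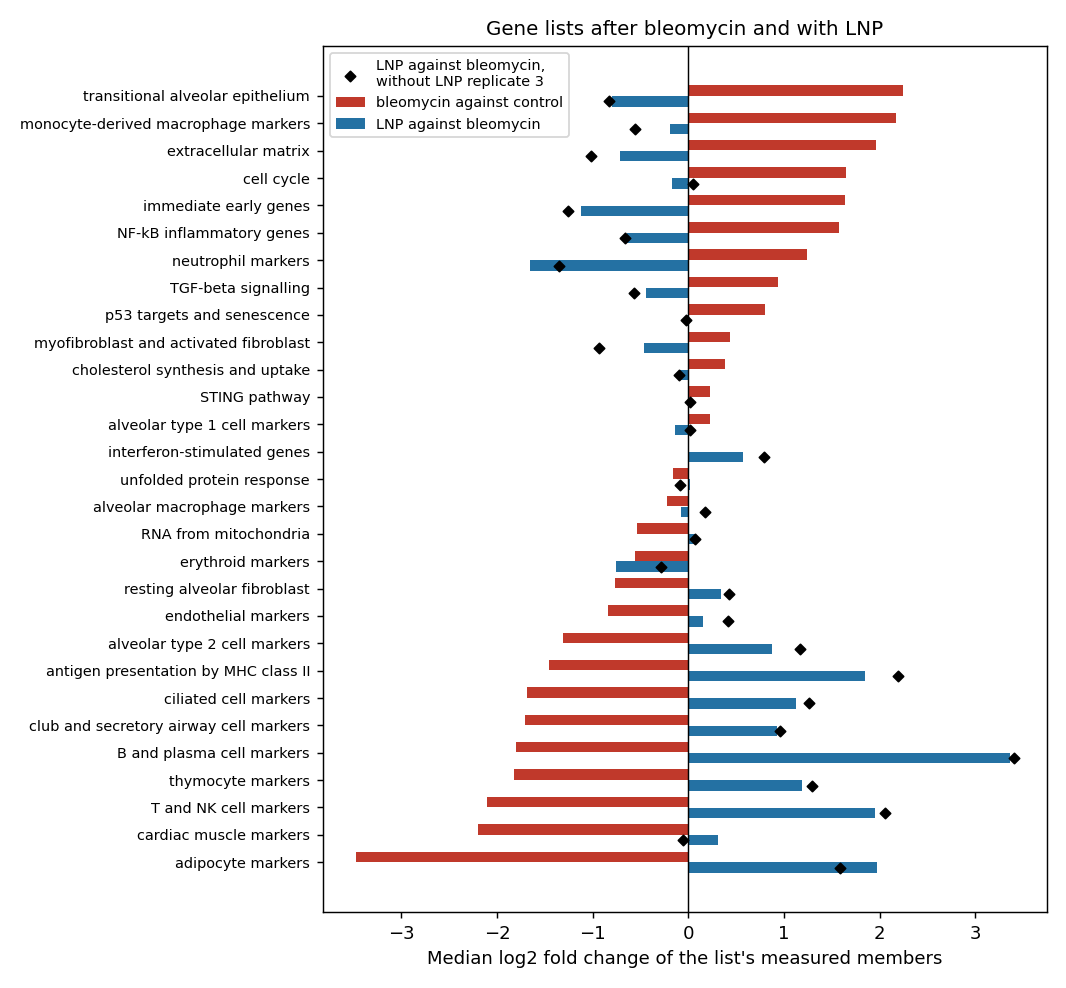
Bars give the median log2 fold change (x axis) of each list's measured members for bleomycin against control and for LNP against bleomycin, and diamonds the second value without LNP replicate 3; the skeletal muscle list, with a median of 6.82 that LNP replicate 3 sets, is left out of the drawing. B and plasma cell markers stood at -1.80 after bleomycin and at 3.36 with LNP.

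Whether the particles moved genes back toward control was asked by setting both comparisons side by side. Of the genes higher after bleomycin, 339 were lower in LNP than in bleomycin lung, and of the genes lower after bleomycin, 779 were higher, while 8 changed the same way in both comparisons. Lists of those sizes drawn independently would share 59.1 and 165 genes. The genes that rose and then were lower were led by S100a8, Retnlg, Trem1, Stfa2l1, Olfm4, S100a9, Mxd1 and Btg2. Those that fell and then were higher included Ighd, Cd79a, Blk, Cd79b, H2-Ob, Fcmr and Spib. Both comparisons use the bleomycin libraries with opposite signs, so opposite changes also arise by chance. In 20 simulations that kept the bleomycin effect and gave LNP libraries the bleomycin means, the correlation of the log2 fold changes over all genes averaged -0.18, against an observed -0.67, and the covariance -0.13 against -0.99. With all groups at one mean the correlation was -0.50 and the covariance -0.14. The median log2 fold change in LNP against bleomycin was -0.45 among genes that had risen and 0.67 among genes that had fallen. Simulations with LNP at the bleomycin means gave -0.067 and 0.071. Those with all groups at one mean gave -1.53 and 2.87, larger than observed, among the genes called there by chance. With no real effect present, those medians cover false calls only, so they give no level for genes that bleomycin did change. In the simulations with LNP at the bleomycin means the overlap counts averaged 0 and 0.05, against 339 and 779. The simulated genes were drawn independently. A group of 3 libraries cannot be split into parts of at least 2 libraries each, so part of the excess may come from the shared libraries. The counts of 339 and 779 became 17 and 82 without bleomycin replicate 2 and 1863 and 2499 without LNP replicate 3. In that last fit independent lists would share 470.1 and 661 genes, against the 1863 and 2499, and 66 genes changed the same way in both comparisons. Leaving out bleomycin replicate 1 gave 38 and 176, LNP replicate 1 gave 38 and 201, LNP replicate 2 gave 52 and 263, control replicate 1 gave 148 and 471, control replicate 3 gave 131 and 446, and bleomycin replicate 3 gave 466 for the genes that fell and then were higher.

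The third comparison asked how far lung given both treatments stayed from control lung. Most matrix, recruited macrophage, cell cycle and p53 genes were higher in LNP than in control lung, and 6 of 14 club cell, 7 of 12 cardiac muscle and 4 of 19 endothelial markers were lower. Timp1 was at 7.69 ± 1.95 CPM in control and 141 ± 38.2 CPM in LNP lung (log2 fold change 4.19 ± 0.33, adjusted p = 0.00024), and Trem2 at 4.09 ± 1.15 and 98.1 ± 41.5 CPM (log2 fold change 4.58 ± 0.33, adjusted p = 0.00018). Of the B and plasma cell markers, 7 of 17 were above control, with Igkc at 109 ± 13.6 and 453 ± 6.8 CPM (log2 fold change 2.05 ± 0.13, adjusted p = 9.8e-05). In all, 1030 genes were higher and 641 lower, and 5997 genes (28.8%) had no overlap between the groups, where chance gives 10%. Without LNP replicate 3 the counts were 1369 and 963, and 1490 of the 1671 genes called with all libraries were called in both fits.

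The largest rises over control were Jsrp1, Krt4, Ighg2c, Pkp1, Serpinb12, Saa3, H19 and Sprr2a2. Jsrp1 had no count in the control libraries and was at least 634-fold higher against a floor of 3 counts over the group. LNP replicate 3 set the mean of Jsrp1, Krt4, Pkp1, Serpinb12 and H19, at 27.7, 767, 31.2, 29.8 and 193 CPM. Saa3, an acute-phase gene, was at 0.955 ± 0.0639 CPM in control, 90.4 ± 10 CPM in bleomycin and 86 ± 45.2 CPM in LNP lung. The largest falls were Asgr1, Ankrd63, Hes2, Bex2, Plin1, Cyp1a1, Gria1 and Colq, with log2 fold changes from -3.68 to -2.64.

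Extracellular matrix genes were higher than control in 17 of 25 cases and lower in none (23 and 1 over the list alone, camera adjusted p = 3.2e-15, and adjusted p = 0.16 with an estimated correlation). The STING pathway list had 4 of 16 higher, Sting1, Ifi204, Enpp1 and Nlrc3 (5 higher and 1 lower over the list alone, camera adjusted p = 0.019, and adjusted p = 0.16 with an estimated correlation). Of these, Ifi204, Enpp1 and Nlrc3 passed in 8, 6 and 3 of the 9 fits that left out 1 library. Interferon-stimulated genes were higher in 12 of 30 cases (14 over the list alone, camera adjusted p = 6.2e-09, and adjusted p = 0.19 with an estimated correlation), and in 20 without LNP replicate 3. Oas3 was at 2.85 ± 0.418 CPM in control and 14.2 ± 1.24 CPM in LNP lung, and Cxcl10 at 1.54 ± 0.485 and 12.2 ± 1.09 CPM. Monocyte-derived macrophage markers were higher in 15 of 21 cases, also over the list alone (camera adjusted p = 9.0e-14, and adjusted p = 0.087 with an estimated correlation), cell cycle genes in 18 of 23 (23 over the list alone, camera adjusted p = 2.1e-15, and adjusted p = 0.16 with an estimated correlation), p53 targets in 10 of 18 (13 over the list alone, camera adjusted p = 1.5e-09, and adjusted p = 0.061 with an estimated correlation) and transitional epithelium genes in 11 of 13 (12 over the list alone, camera adjusted p = 3.0e-10, and adjusted p = 0.16 with an estimated correlation). NF-kB inflammatory genes were higher in 8 of 22 cases (13 over the list alone, camera adjusted p = 6.6e-06, and adjusted p = 0.27 with an estimated correlation) and TGF-beta signalling genes in 4 of 18, with 1 lower (11 and 2 over the list alone, camera adjusted p = 0.0028, and adjusted p = 0.19 with an estimated correlation). B and plasma cell markers were higher in 7 of 17 cases, also over the list alone (camera adjusted p = 0.00011, and adjusted p = 0.087 with an estimated correlation), led by Igkc, Ighg1, Jchain and Ighg2b. T and NK cell markers had 1 of 19 lower, the cytotoxic gene Prf1 (2 higher and 1 lower over the list alone, camera adjusted p = 0.087).

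Club and secretory markers were lower in 6 of 14 cases and higher in 2, also over the list alone (camera adjusted p = 0.0038, and adjusted p = 0.31 with an estimated correlation), ciliated markers lower in 2 of 15 (7 over the list alone, camera adjusted p = 8.3e-05, and adjusted p = 0.28 with an estimated correlation), endothelial markers in 4 of 19 (10 over the list alone, camera adjusted p = 3.0e-05, and adjusted p = 0.27 with an estimated correlation) and resting fibroblast genes in 4 of 12 (8 over the list alone, camera adjusted p = 0.00049, and adjusted p = 0.27 with an estimated correlation). Cardiac muscle markers were lower in 7 of 12 cases (9 over the list alone, camera adjusted p = 3.4e-06, and adjusted p = 0.27 with an estimated correlation), adipocyte markers in 2 of 9, also over the list alone (camera adjusted p = 0.0042, and adjusted p = 0.21 with an estimated correlation), and mitochondrial transcripts in 3 of 11 (5 over the list alone, camera adjusted p = 0.0022, and adjusted p = 0.45 with an estimated correlation). Erythroid markers were called as lower with no member past the test, in edgeR or DESeq2 and none at an unadjusted p under 0.05, and limma on FPKM called 1 (camera adjusted p = 0.018, and adjusted p = 0.54 with an estimated correlation). Skeletal muscle markers were not called (camera adjusted p = 0.1), with no member past the test over all genes and 10 of 11 over the list alone, where DESeq2 called 0, and without LNP replicate 3 they were called as lower (camera adjusted p = 0.02). That fit put 8 TGF-beta and 2 resting fibroblast genes higher, and 7 endothelial, 11 cardiac muscle and 3 skeletal muscle genes lower. Of the T and NK cell markers it put 1 higher and 2 lower.

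The myofibroblast, alveolar macrophage, neutrophil, alveolar type 1 and type 2, cholesterol, unfolded protein response, immediate early and thymocyte lists were not called against control, at camera adjusted p-values of 0.36, 0.65, 0.28, 0.56, 0.081, 0.062, 0.16, 0.12 and 0.12. Among neutrophil genes S100a8 and S100a9 were lower than control and Lcn2 higher (6 lower and 3 higher adjusted over the list alone), and S100a8 stood at 24.4 ± 3.4 CPM in control. MHC class II genes had 1 of 8 higher, H2-Oa, also over the list alone (camera adjusted p = 0.12). H2-Oa passed against control in 2 of the 9 fits that left out 1 library. With LNP replicate 3 left out, 7 of the 8 were higher and the list was called (camera adjusted p = 2.3e-05), as were alveolar type 1 markers (camera adjusted p = 0.041) and cholesterol genes (camera adjusted p = 0.037). The same fit put 6 myofibroblast genes lower in place of 1 and 5 alveolar type 1 markers higher in place of 1. It also put 2 neutrophil genes higher, and 2 alveolar macrophage, 2 immediate early, 1 alveolar type 2 and 1 cholesterol gene lower. Erythroid markers were then not called (camera adjusted p = 0.17).

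The overlap of both comparisons against control was 900 genes higher in each and 580 lower in each, where independent lists would share 156 and 118 genes, and 8 genes changed in opposite directions. Both share the control libraries. The correlation of their log2 fold changes was 0.72 and the covariance 1.13, against 0.50 and 0.14 in simulations with no effect in either group. Without LNP replicate 3 the correlation was 0.56 and the covariance 0.95. In that fit 1089 genes were higher in each and 708 lower in each, where independent lists would share 280.2 and 213 genes. Another 109 genes then changed in opposite directions. The simulations were run only with all 9 libraries. The controls cannot be split into parts of at least 2 libraries each, so part of the excess may come from the shared controls. Leaving out control replicate 1 gave 491 higher and 226 lower genes against control, bleomycin replicate 2 gave 357 lower genes, LNP replicate 2 gave 298 lower genes and control replicate 3 gave 519 higher and 262 lower genes. Of the 99 gene results selected by the naming rule for this comparison, 66 passed the test whichever library was left out, among them Timp1, Trem2, Spp1, Igkc, Oas3 and Cxcl10.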

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

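The fits with library weights and with library-size scaling were chosen after the results were seen, and the other alternatives were planned. The library weights ran from 0.13 for LNP replicate 3 to 9.97 for bleomycin replicate 2. The weighted fit's bleomycin values therefore rest largely on that 1 library. No gene result selected by the naming rule reversed under any alternative. Of 303 such results, 298 kept their call with DESeq2, 302 with relative log expression, 293 with library-size scaling, 281 without a count filter, 245 with only the 2 groups, and 299 with library weights, and of 2727 results with 1 library left out, 379 lost it. With 3 libraries a group, edgeR missed most 2-fold changes in simulated data, so counts of calls depend on the estimate of the spread; beyond fewer libraries or higher thresholds, the cause of each difference was not tested.

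Bleomycin against control gave 5824 higher and 6940 lower genes with library weights, 1700 and 2317 with a 2-fold minimum, and 1656 and 1336 transcripts tested singly. LNP against bleomycin gave 1930 and 1081 with DESeq2, 218 and 100 with only the 2 groups, 403 and 136 with unfiltered FPKM, 5811 and 5098 with library weights, and 58 and 23 transcripts. Its lower genes numbered 197 without a count filter, 166 with a 2-fold minimum and 253 with library-size scaling. LNP against control gave 1816 and 1122 with DESeq2, 679 and 331 with only the 2 groups, 2657 and 2901 with library weights, and 237 and 53 transcripts, with 299 lower at a 2-fold minimum. Genes higher after bleomycin and then lower with LNP numbered 921 with DESeq2, 174 without a count filter and 142 with a 2-fold minimum, and genes that went the other way 1577 with DESeq2.

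With the replicate number as a replicate block, LNP against bleomycin gave 346 higher and 86 lower genes and LNP against control 401 lower, with 82 genes higher and then lower and 307 lower and then higher. Bleomycin against control gave 2758 higher and 3385 lower genes. The numbers do not pair the libraries: same-numbered libraries deviated from their group means with correlations from -0.018 to 0.04, and 1 library of 9 correlated best with its own number.

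Sting1 in LNP against bleomycin was 0.4487 with library weights (adjusted p 0.0024) and ran from 0.0853 to 0.4487 over all alternatives, with adjusted p from 0.0024 to 1.

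Leaving out 1 library at a time moved genes higher after bleomycin between 1951 and 4374 and lower between 2412 and 4728. LNP against bleomycin ran from 84 to 2987 higher and from 18 to 2297 lower, with the lowest values without bleomycin replicate 2 and the highest without LNP replicate 3. LNP against control ran from 491 to 1369 higher and from 226 to 963 lower, lowest without control replicate 1 and highest without LNP replicate 3. Genes higher after bleomycin and lower with LNP ran from 17 to 1863, and the other way from 82 to 2499.

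With an estimated correlation, 0 lists were called for bleomycin against control, 1 for LNP against bleomycin and 0 for LNP against control. The extracellular matrix list then had adjusted p = 0.1495, 0.1952 and 0.1638, the STING pathway list 0.1638 for LNP against control, and interferon-stimulated genes 0.262 for LNP against bleomycin and 0.1852 for LNP against control. By fry, which tests whether the genes of a list move 1 way, the STING pathway after bleomycin had adjusted p = 0.0001007, within a range of 0.0001007 to 0.2371 over its alternatives. Endothelial markers in LNP against bleomycin ran from 0.0394 without LNP replicate 3, where they turned upward, to 0.8151 without bleomycin replicate 3 with 1 library left out, and up to 0.9773 by fry. Skeletal muscle markers ran from 0.0006542 without LNP replicate 1 to 0.7805 without LNP replicate 3, where they turned downward, and against control from 0.00815 without LNP replicate 1 to 0.1952 without control replicate 2 with 1 library left out, with a downward turn at 0.02011 without LNP replicate 3, and up to 0.6408 with an estimated correlation.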

Other observations

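The tests of LNP replicate 3 against a squamous change and against a sample that is not lung, of dilution, and of the interferon-stimulated genes without LNP replicate 3 were chosen after the result was seen, and a requirement was added afterwards to the test at equal lymphocyte score. The genes of the next paragraph were chosen after their values were seen, by the smallest values of the larger p of both comparisons among genes at 5 CPM or more.

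LNP lung also held transcripts at levels that neither other group had. At an adjusted p under 0.05 in edgeR in both comparisons, 62 genes were higher and 14 lower in LNP than in both control and bleomycin lung, all 76 without overlap between the libraries. The 6 higher genes with the smallest p begin with Igkc at 109 ± 13.6 CPM (SD) in control, 96.7 ± 7.95 CPM in bleomycin and 453 ± 6.81 CPM in LNP. Ccl21a, a chemokine of lymphatic vessels, was at 93.8 ± 13.6, 112 ± 11.6 and 226 ± 16.4 CPM, and Ighg2c at 0.282 ± 0.142, 1.06 ± 0.366 and 62.7 ± 70.9 CPM. Apobec3 was at 56.2 ± 0.772, 53.6 ± 1.11 and 89.0 ± 5.57 CPM, and the squamous gene Sprr2a1 at 0.253 ± 0.0569, 2.16 ± 0.523 and 15.7 ± 9.78 CPM. Jchain, which joins secreted antibody units, was at 14.3 ± 2.95, 18.1 ± 3.77 and 68.1 ± 27.2 CPM. Ighg2c, Sprr2a1 and Ccl21a have near-identical copies, so their values are uncertain, and Ighg2c and Sprr2a1 were highest in LNP replicate 3. Ccl21e, of the Ccl21a family, was at 15.5 ± 2.67, 20.3 ± 2.57 and 37.7 ± 6.91 CPM. The 3 lower genes with the smallest p were S100a8 at 24.4 ± 3.4, 82.5 ± 25.9 and 9.5 ± 2.19 CPM, Adgrl3 at 34.8 ± 6.15, 27.7 ± 1.76 and 15.99 ± 1.36 CPM, and Dennd3 at 155 ± 15.3, 162 ± 12.4 and 99.5 ± 11.6 CPM.

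LNP replicate 3 held squamous and skeletal muscle transcripts. Tissue from outside the lung, such as oesophagus, is a candidate explanation: over 15 oesophageal squamous markers not looked at before, the median ratio of this library to the highest of the other 8 was 22.9 (22.89), and 10 of 15 were over 4 times. A squamous change of the airway lining alone leaves muscle genes unmoved, but the muscle markers had a median ratio of 142.8, with 11 of 11 over 4 times. A sample that is not lung is argued against by 40 lung epithelial markers, whose median was 107.3% of the lowest other library. No biological explanation by the treatment was tested, and it stays open.

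Most lymphocyte markers were low in the bleomycin libraries and higher in the LNP libraries, where 7 of 17 B and plasma cell markers, among them Igkc, were above control. Dilution by other RNA alone would lower endothelial and alveolar type 1 markers alike, yet lymphocyte markers fell further, with a difference of medians of -1.80 (-1.8044, 95% bootstrap interval -2.97 to -1.07). The interval resamples genes and does not measure the spread between libraries. The endothelial and alveolar type 1 lists themselves differed, with medians of -0.84 and 0.22, so they do not measure dilution. Dilution as a part of the fall is therefore not excluded. Glucocorticoid exposure of the bleomycin mice could lower lymphocytes, but of 8 induced genes 1, Errfi1, passed as higher after bleomycin and lower with LNP, with medians of 0.88 and -0.70. Of the other 7, 2 passed as higher after bleomycin, Zbtb16 passed as lower (log2 fold change -1.38, adjusted p = 0.0441) and Tsc22d3 was at -0.10, so the genes went both ways and leave it open. Lymph node tissue in the control and LNP libraries may add such RNA, and its 5 tested genes had a median of 1.01 (1.013) in LNP against bleomycin, between the bounds of 1 and 2 set beforehand. Of these genes, Ccl19 (log2 fold change 2.98, adjusted p = 0.0153) and Ccl21a (1.01, adjusted p = 0.0082) passed as higher in LNP than in bleomycin. Madcam1 (2.19), Cxcl13 (0.68) and Chst4 (-0.24) did not pass there. The median of the 5 genes was 0.25 in bleomycin against control, where Ccl19 passed as lower but Cxcl13 and Madcam1 as higher. The genes thus went both ways after bleomycin, which leaves lymph node tissue open. Adipocyte markers had medians of -3.48 after bleomycin and 1.97 in LNP against bleomycin, and thymocyte markers -1.82 and 1.19. Cardiac muscle markers were at -2.20 and 0.315, the latter not called. Whether other tissue brought lymphocyte RNA into the control and LNP libraries was not tested. An effect of bleomycin and of the particles on lymphocyte number stays open too.

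Of 30 interferon-stimulated genes, 5 passed as higher in LNP than in bleomycin lung, and the list was called as higher with the preset correlation but not with an estimated one (adjusted p = 0.262). LNP replicate 3 alone does not account for it, since its mean log2 CPM of the list, 4.43, was the lowest of the LNP libraries. LNP replicates 1 and 2 were at 4.93 and 4.82 and the bleomycin libraries at 4.12 to 4.22. Without LNP replicate 3 the list's camera adjusted p was 1.1e-06 (1.122e-06), within a range from 1.03e-06 to 0.262 over its alternatives. The list was not called with an estimated correlation, so the p with the preset correlation by itself excludes nothing. More lymphocyte RNA in the LNP libraries could account for the higher list: at equal lymphocyte score the difference of mean log2 CPM was -1.01 (-1.0072, 95% interval -2.47 to 0.46), against 0.56 (0.17 to 0.94) by group alone. This met the prediction for that cause with all 9 libraries. Control libraries had lymphocyte scores of 3.11 to 3.24, within the 2.86 to 3.60 of the LNP libraries. The mean log2 CPM of the list was 3.68 to 4.07 in control and 4.43 to 4.93 in LNP libraries. A like lymphocyte score without bleomycin thus went with a lower level. Control mice received no bleomycin, so this does not test whether lymphocyte RNA accounts for the difference between LNP and bleomycin libraries. The slope on the score rests on LNP replicate 3, with an interval of 0.05 to 1.22 with it and -2.89 to 3.81 without it. The requirement that the slope hold without that library was added after the result was seen, so lymphocyte RNA and an effect of the particles cannot be told apart.

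The 10 splits into 3 and 3 libraries are too few for a share under 0.05, so only values are given. For genes changed the real split gave 7002, 1280 and 1671 for bleomycin against control, LNP against bleomycin and LNP against control, the highest other split gave 0, 1 and 0, and 1 of the 10 splits, the real one, gave as many each time. For gene lists called with the preset correlation the real split gave 23, 17 and 18, the highest other 18, 19 and 16, and 1, 3 and 1 of 10 splits gave as many. Mixed splits thus called nearly as many lists as the real one, and more for LNP against bleomycin. Each mixed split keeps part of the real difference and widens the spread within its groups. Neither the genes nor the lists called in the other splits therefore give a chance level.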
